A study of Mus musculus with 9 samples.

How the data were processed

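Total RNA of T6E cells was extracted with a column kit, labelled with biotin and hybridised to single-colour arrays, per the labels' protocols. Cells were held in DMSO or in 1 μM GSI for 24 h and then replated for 6 h with 20 μg/mL cycloheximide, the former in DMSO and the latter in GSI (GSI group) or in DMSO (WASH group), per the labels' protocols. Each group holds 3 arrays, taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The arrays were processed with oligo, an R package for such arrays, per the submitters' processing notes. Its version, the background correction, the normalization and the summarization method are not given in the sources used here. The authors deposited 1 table with 1 value per probe set and array, taken here as log2 because the values run from 3.14 to 13.9. The base is not stated, so every log2 change and fold rests on that reading. The array medians lay within 6.40 to 6.42, as in values already normalized between arrays, so no further normalization was applied. The table held 0 columns of other samples.

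The table held 41345 probe sets. In the platform annotation 23521 had 1 gene symbol, 1820 had several and 16004 were not listed. Probe sets with several symbols or none were left out of gene tests. Where a symbol had more than 1 probe set (1082 symbols), the one with the highest mean over all 9 arrays was kept, which left 22180 genes. No symbol had probe sets called in both directions in any comparison. Dim probe sets were not removed. Genome coordinates are not printed, because the build behind the table is not named.

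For each gene limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 9 arrays, with moderated variances (eBayes), and 3 contrasts were drawn: GSI minus DMSO, WASH minus GSI, and WASH minus DMSO. All groups share the estimate of the spread, with 6 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are limma's standard errors. The recovered share of a gene is its WASH minus GSI change as a percent of its loss with GSI. The simulations with shared GSI arrays drew 100 sets of arrays with no change, and 50 sets with the GSI effects kept.

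There were 22 gene lists, with 584 entries of which 500 were measured, 12 of them found through the gene identifier. They cover Notch targets, the Notch pathway, MAF and ETS factors, ribosome biogenesis, anabolic metabolism, glycolysis, the cell cycle, apoptosis, T-cell genes, FOXO and KLF2 quiescence, immediate early genes, the integrated stress response, ribosomal proteins, interferon, cholesterol, p53 targets, histones, and markers of B, myeloid, erythroid, NK and stromal cells. Under 80% of members were measured for the histone, erythroid, B-cell and cholesterol lists, so these speak only for the measured part. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 22 lists and 3 contrasts, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes. Fry tests whether the list's genes move on balance one way, and does not compare them with other genes. Median, mean and test direction had 1 sign in each list that was called. They differed in sign in some lists that were not called, among them the Notch pathway, p53, NK, stromal, erythroid, myeloid, glycolysis and integrated stress lists in WASH against GSI.

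The genes named in the text follow a fixed rule. It takes, per contrast, the 10 highest and 10 lowest log2 changes among called genes whose groups do not overlap, passing over predicted models, small RNAs and olfactory or vomeronasal receptors. It then takes the 10 genes that fell and rose with the largest smaller change, up to 5 that rose and fell, every measured Notch target, Mafb, Maf, Ets1, Ets2 and Myc, and up to 4 members of each other list with the smallest p. Other called list members are named as examples of their list. The design, the lists, the naming rule and the alternative settings were fixed before the data were examined.

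Alternatives were the replicate number as a block, a fit on only the 6 arrays compared, eBayes with trend and robust, array weights, quantile normalization, median centring, a filter on dim genes, the mean of all probe sets of a gene, all probe sets, an adjusted p of 0.01, a fold minimum of 1.5, and each array left out in turn. Cyclic loess was added after the data had been seen.

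The labels number the arrays 1 to 3 in each group without saying what a number marks. Deviations of same-numbered arrays from their group means correlated at 0.154, 0.161 and 0.273 for DMSO and GSI, at 0.207, 0.190 and 0.0668 for DMSO and WASH, and at 0.255, -0.0199 and 0.149 for GSI and WASH. All 9 arrays correlated best with an array of their own number. With each of its 3 pairs above 0.1, GSI against DMSO was taken as paired by the data, and its blocked values are given where they change a call. That reading by comparison was made after the calls with and without the block had been compared. The block called 2032 genes there, against 1582 without it. The other comparisons, and the overlaps that rest on them, were not taken as paired. As all 9 arrays matched their own number best, an effect of the number on the WASH arrays stays open. With the block WASH against GSI called 359 genes in place of 245, and WASH against DMSO 1817 in place of 1384. Blocked counts of list members were made only for GSI against DMSO, so those of the other comparisons were not checked against it. Counts, errors and p-values are from the fit without the block unless the block is named.

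The scripts were tested on simulated data for the 22180 genes, with real means and 200 genes changed in GSI arrays only. Noise was normal, with limma's moderated variances, and independent between arrays, so it held no effect of the replicate number. The smallest change set was 0.5, above the median size of 0.334 among genes called in GSI against DMSO. The shares below therefore do not speak for smaller changes. In GSI against DMSO the test called 86.6% of 67 genes changed by 0.5 log2 units, 97.0% of 67 changed by 1 and 100% of 66 changed by 2. In WASH against GSI the shares were 94.0, 97.0 and 100%. Unchanged genes made up 6.44% of the calls in the first comparison and 6.73% in the second, and none of the 200 was called in WASH against DMSO, where they did not differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.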

Results

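Gene expression was measured on 9 single-colour arrays of T6E cells, a mouse T-cell acute lymphoblastic leukaemia (T-ALL) line in which Notch signalling can be switched off with a gamma-secretase inhibitor (GSI). GSI blocks the proteolytic step that releases the active intracellular part of the Notch receptor. The arrays fell into 3 groups of 3. Cells in the DMSO group received solvent throughout, cells in the GSI group received 1 μM inhibitor for 30 h, and cells in the WASH group received it for 24 h and then solvent for 6 h. All 3 groups were replated for the last 6 h in medium with 20 μg/mL cycloheximide, which stops protein synthesis. The array medians lay between 6.40 and 6.42 on a scale taken as log2, and 22180 genes were tested. Any 2 arrays of a group correlated at 0.997 to 0.999 across genes, and any 2 arrays of different groups at 0.995 to 0.998. The first principal component (36.3% of the variance) separated the DMSO arrays from the other 6, and the second (21.0%) separated GSI from WASH. The number of arrays limits the precision of every value below.

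The comparison of GSI with DMSO asked what changed when Notch signalling was inhibited, with cycloheximide in both groups for the last 6 h. Inhibition without cycloheximide was not measured. Among the genes that rose were Spib, an ETS-family transcription factor, by 2.55 ± 0.19 log2 units (SE, n = 3 arrays per group; adjusted p = 0.000111), and 3 guanylate-binding protein genes, Gbp8 (2.34 ± 0.18), Gbp4 (2.03 ± 0.11) and Gbp9 (1.82 ± 0.11). Madcam1, which encodes a mucosal adhesion molecule, rose by 2.12 ± 0.08 and Susd2 by 1.84 ± 0.11. Also higher were the membrane protease gene Hpn (1.80 ± 0.11) and the prostaglandin E receptor gene Ptger3 (1.76 ± 0.21). Gramd3 and Prnd each rose by 1.61, with SEs of 0.17 and 0.08. The metallothionein gene Mt2 fell by 2.39 ± 0.04 (adjusted p = 5.42e-09), from 10.78 ± 0.03 (SD, n = 3) to 8.38 ± 0.03, a 5.26-fold loss. The glycosyltransferase gene B4galnt2 fell by 2.39 ± 0.11, the cytokine gene Il10 fell by 1.96 ± 0.15, and Serpinb8 fell by 1.89 ± 0.09. The decoy receptor gene Tnfrsf23 fell by 1.80 ± 0.37, and the gene for the mTOR inhibitor Deptor fell by 1.67 ± 0.11. Aox1 fell by 1.44 ± 0.11, the interleukin-2 receptor gene Il2ra by 1.38 ± 0.10, the receptor tyrosine kinase gene Ret by 1.34 ± 0.20 and Ifi202b by 1.31 ± 0.27. In all, 768 genes rose and 814 fell at an adjusted p below 0.05 in limma's moderated test, and 41 and 24 of them by at least 2-fold. Without GSI replicate 3 the total of 1582 became 722 (390 higher, 332 lower), without DMSO replicate 3 it became 949 (458 and 491), and without GSI replicate 1 it became 1010 (557 and 453). The call of Tnfrsf23 was lost without GSI replicate 1, DMSO replicate 3 or GSI replicate 3 (adjusted p up to 0.0704), and that of Ifi202b without DMSO replicate 1, GSI replicate 2, DMSO replicate 3 or GSI replicate 3 (up to 0.0725).

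Of 21 measured Notch target genes, 6 fell with GSI and none rose, and the count was the same when adjusted over the list alone. The fallen members were Il2ra, the E3 ligase gene Dtx1 (by 1.31 ± 0.09), the transcriptional repressor gene Hes1 (by 1.26 ± 0.18), the receptor gene Notch3 (by 0.86 ± 0.10), the Notch feedback regulator Nrarp (by 0.81 ± 0.15) and Hey1 (by 0.29 ± 0.06). Camera placed the list lower than other genes (adjusted p = 0.000184), and the call was lost with adjusted p = 0.225 with an estimated correlation. The values for Myc (-0.07 ± 0.08, adjusted p = 0.735) and Notch1 (-0.07 ± 0.08, adjusted p = 0.720), as for Hes5 (-0.32 ± 0.38), Heyl (-0.67 ± 0.25), Ptcra (-0.32 ± 0.14) and Trib2 (-0.02 ± 0.06), did not pass. Nor did those of Cdkn1a (-0.61 ± 0.24), Ccnd1 (0.16 ± 0.06), Gata3 (0.06 ± 0.07), Il7r (0.00 ± 0.05), Lef1 (0.02 ± 0.05), Hey2 (0.05 ± 0.08), Ccnd3 (-0.05 ± 0.04), Bhlhe40 (0.10 ± 0.08) and Igf1r (-0.00 ± 0.10). Cells of both groups had cycloheximide, so the values for Myc, Notch1 and the others do not speak for inhibition without it. With the replicate number as a block, Heyl (adjusted p = 0.0304) and Cdkn1a (adjusted p = 0.0157) also passed, so that 8 of 21 were lower. Hey1 lost its call without GSI replicate 1, DMSO replicate 3 or GSI replicate 3 (adjusted p up to 0.0697), and Nrarp without GSI replicate 3 (0.0577). Among 34 genes of the Notch pathway itself, Maml2, a coactivator of the Notch transcription complex, rose by 0.88 ± 0.11, Notch2 by 0.68 ± 0.08 and the fringe glycosyltransferase gene Mfng by 0.23 ± 0.06, while Notch3 fell. With the block Jag1 was also lower (adjusted p = 0.00304) and Pofut1 higher (adjusted p = 0.0436). That list did not pass as a group (adjusted p = 0.388; 5 higher and 2 lower adjusted over the list alone), and Mfng kept its call only without WASH replicate 1 or WASH replicate 3 (adjusted p up to 0.132 without another array). Mafb, the factor named in the study's title, was not analysed here, since no probe set carried its symbol alone. Of 21 other MAF and ETS factor genes, Maf rose by 0.65 ± 0.10 (adjusted p = 0.00441), Etv6 by 0.39 ± 0.06 and Elk3 by 0.33 ± 0.06, and none fell (6 and 0 adjusted over the list alone). The list was called higher (adjusted p = 0.000184; adjusted p = 0.125 with an estimated correlation). With the block Elk4 was also higher (adjusted p = 0.0408). The values for Ets1 (-0.05 ± 0.09) and Ets2 (0.08 ± 0.05) did not pass, and Elk3 lost its call without GSI replicate 3 (adjusted p = 0.0621).

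Of 159 genes in 6 lists of growth and division, 52 fell with GSI and 3 rose. In the S phase, G2 and mitosis list 14 of 33 members fell and none rose, among them the cyclin gene Ccne1 (by 0.47 ± 0.06), Mybl2 (by 0.38 ± 0.07), E2f2 (by 0.35 ± 0.06) and the replicative helicase subunit gene Mcm6 (by 0.33 ± 0.05). In the nucleotide, serine and one-carbon synthesis list 11 of 24 fell, including Cad (by 0.42 ± 0.08), Shmt2 (by 0.40 ± 0.04) and Rrm2 (by 0.30 ± 0.04), and Phgdh rose by 0.32 ± 0.06. Of 39 ribosomal protein genes 12 fell, for example Rps13 (by 0.33 ± 0.04) and Rpl13 (by 0.31 ± 0.05). Of 34 ribosome biogenesis genes 5 fell, including Npm1 (by 0.28 ± 0.04) and Heatr1 (by 0.25 ± 0.04), while Gnl3 rose by 0.39 ± 0.08. Of 17 glycolysis genes 5 fell, with Tpi1 (by 0.65 ± 0.11) and Pkm (by 0.29 ± 0.05) among them, and Hk1 rose by 0.21 ± 0.04. Of the 12 replication-dependent histone genes that were measured, out of 29 listed, 5 fell, with H4c14 (by 0.73 ± 0.11) and H1f5 (by 0.38 ± 0.07) among them. Adjusted over the list alone, the fallen members were 21 in the cell cycle list, 16 in the anabolic list, 18 among ribosomal proteins, 11 in ribosome biogenesis, 6 in glycolysis and 10 among histones. Camera called the cell cycle (adjusted p = 3.58e-13), ribosomal protein (6.89e-12), anabolic (2.80e-08), histone (3.60e-08), ribosome biogenesis (5.24e-06) and glycolysis (0.00125) lists lower. With an estimated correlation the adjusted p was 0.125 for cell cycle, 0.149 for the ribosomal protein, anabolic and histone lists, 0.374 for ribosome biogenesis and 0.359 for glycolysis, so none of the 6 camera calls held. Fry, which does not compare a list with other genes, called all 6 lower. Its adjusted p ran from 0.00345 for cell cycle to 0.0381 for ribosome biogenesis. With the replicate number as a block, 10 ribosome biogenesis and 8 histone genes were lower, 15 in the cell cycle list and 6 in glycolysis. The anabolic and ribosomal protein counts were 11 and 12 with it too, although Srm (adjusted p = 0.0652) and Rpl37 (adjusted p = 0.0524) lost their calls. Gnl3 lost its call without GSI replicate 3 (adjusted p = 0.0686).

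Of 28 measured immediate early genes, 6 rose with GSI and none fell (9 and 0 adjusted over the list alone). They were Gadd45b (by 1.02 ± 0.20), Tnfaip3 (by 0.86 ± 0.09), Dusp2 (by 0.68 ± 0.08), Nfkbia (by 0.62 ± 0.07), Ier5 (by 0.42 ± 0.08) and Junb (by 0.39 ± 0.06). Nfkbia and Tnfaip3 encode feedback inhibitors of NF-kB. Cycloheximide can raise immediate early genes, and all groups had it. An effect of GSI alone therefore cannot be told apart from a changed response to cycloheximide. The list was called higher (adjusted p = 7.44e-07; adjusted p = 0.419 with an estimated correlation). Among 24 genes of the integrated stress response 7 fell, including Ddit4 (by 0.61 ± 0.06), Aldh18a1 (by 0.56 ± 0.07) and Asns (by 0.37 ± 0.05), and 3 rose, Phgdh, Herpud1 (by 0.24 ± 0.05) and Ddit3 (by 0.19 ± 0.05). Adjusted over the list alone 8 fell and 3 rose. The list was called lower (adjusted p = 0.0136; adjusted p = 0.374 with an estimated correlation), and the first call was lost without DMSO replicate 2 (adjusted p = 0.149). Of 23 apoptosis genes, Birc3 (by 1.27 ± 0.12), Fas (by 0.65 ± 0.14), Bid (by 0.52 ± 0.07) and Bbc3 (by 0.44 ± 0.08) rose (5 higher and 2 lower adjusted over the list alone; list adjusted p = 0.146). Among 28 T-cell genes the costimulatory receptor gene Cd28 fell by 1.25 ± 0.12, and Cd4 (0.82 ± 0.21), Ikzf1 (0.30 ± 0.05), Fyn (0.27 ± 0.04) and Lcp2 (0.20 ± 0.04) rose (6 and 2 adjusted over the list alone; list adjusted p = 0.197). With the replicate number as a block, 9 immediate early genes were higher (Jund, Egr2 and Ier2 added) and 8 integrated stress genes lower (Slc7a11 added). Higher with it too were the apoptosis gene Mcl1 (adjusted p = 0.0218) and the T-cell genes Cd5 (0.00979), Thy1 (0.00392) and Bcl11b (0.0273). Fas lost its call without GSI replicate 2, DMSO replicate 3 or GSI replicate 3 (adjusted p up to 0.0790). Bbc3 lost its call without either replicate 3 of DMSO or GSI (up to 0.0621) and Lcp2 without GSI replicate 1, GSI replicate 2, GSI replicate 3 or DMSO replicate 3 (up to 0.0816).

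The lists for interferon (adjusted p = 0.142; median -0.17; 4 of 26 members higher and 1 lower, but 4 and 6 adjusted over the list alone), cholesterol synthesis (0.196; none of 17 at an adjusted p below 0.05 in limma), FOXO and KLF2 quiescence (0.0659; 1 of 20 higher) and p53 targets (0.580; 3 of 22 higher and 1 lower) were not called with GSI. Under median centring 1 interferon gene was higher and 2 were lower, so the balance of its calls turned with the scaling. Under quantile normalization 2 quiescence genes were higher. Of the cholesterol genes 3 had an unadjusted p below 0.05. The interferon list was called lower without DMSO replicate 1 or DMSO replicate 3 (adjusted p down to 0.0116). The cholesterol list was called lower without DMSO replicate 1 or GSI replicate 2 (down to 0.0124), and the quiescence list higher without DMSO replicate 1, WASH replicate 1, DMSO replicate 2 or GSI replicate 3 (down to 0.0188). With the replicate number as a block, the cholesterol list was called lower (adjusted p = 0.0353; Nsdhl and Msmo1 lower), and 3 interferon genes were higher and 2 lower, with Socs1 lost (adjusted p = 0.0634). Of the quiescence genes 2 were higher with it, and of the p53 targets 4 higher and 2 lower. Markers of other cell types were included as lists. None of 14 B-cell markers and none of 8 erythroid markers, out of 17 listed, passed in limma's test with GSI (2 and 0 at an unadjusted p below 0.05). The myeloid marker Lyz2 fell by 0.56 ± 0.13, the only one of 25 called (1 more was called higher under quantile normalization or cyclic loess). Of 12 NK and cytotoxic markers Tbx21 fell by 0.62 ± 0.06, and of 18 stromal and endothelial markers Madcam1 rose and Pdgfrb fell by 0.65 ± 0.09. With the block the B-cell marker Blnk (adjusted p = 0.00979), the myeloid marker Fcgr3 (0.0383), the NK marker Nkg7 (0.00946) and the endothelial marker Pecam1 (0.00212) were higher, and Ly6g (0.0486) was lower. Lyz2 lost its call without DMSO replicate 1, GSI replicate 2, WASH replicate 2, DMSO replicate 3 or GSI replicate 3 (adjusted p up to 0.134).

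**Figure D1:**
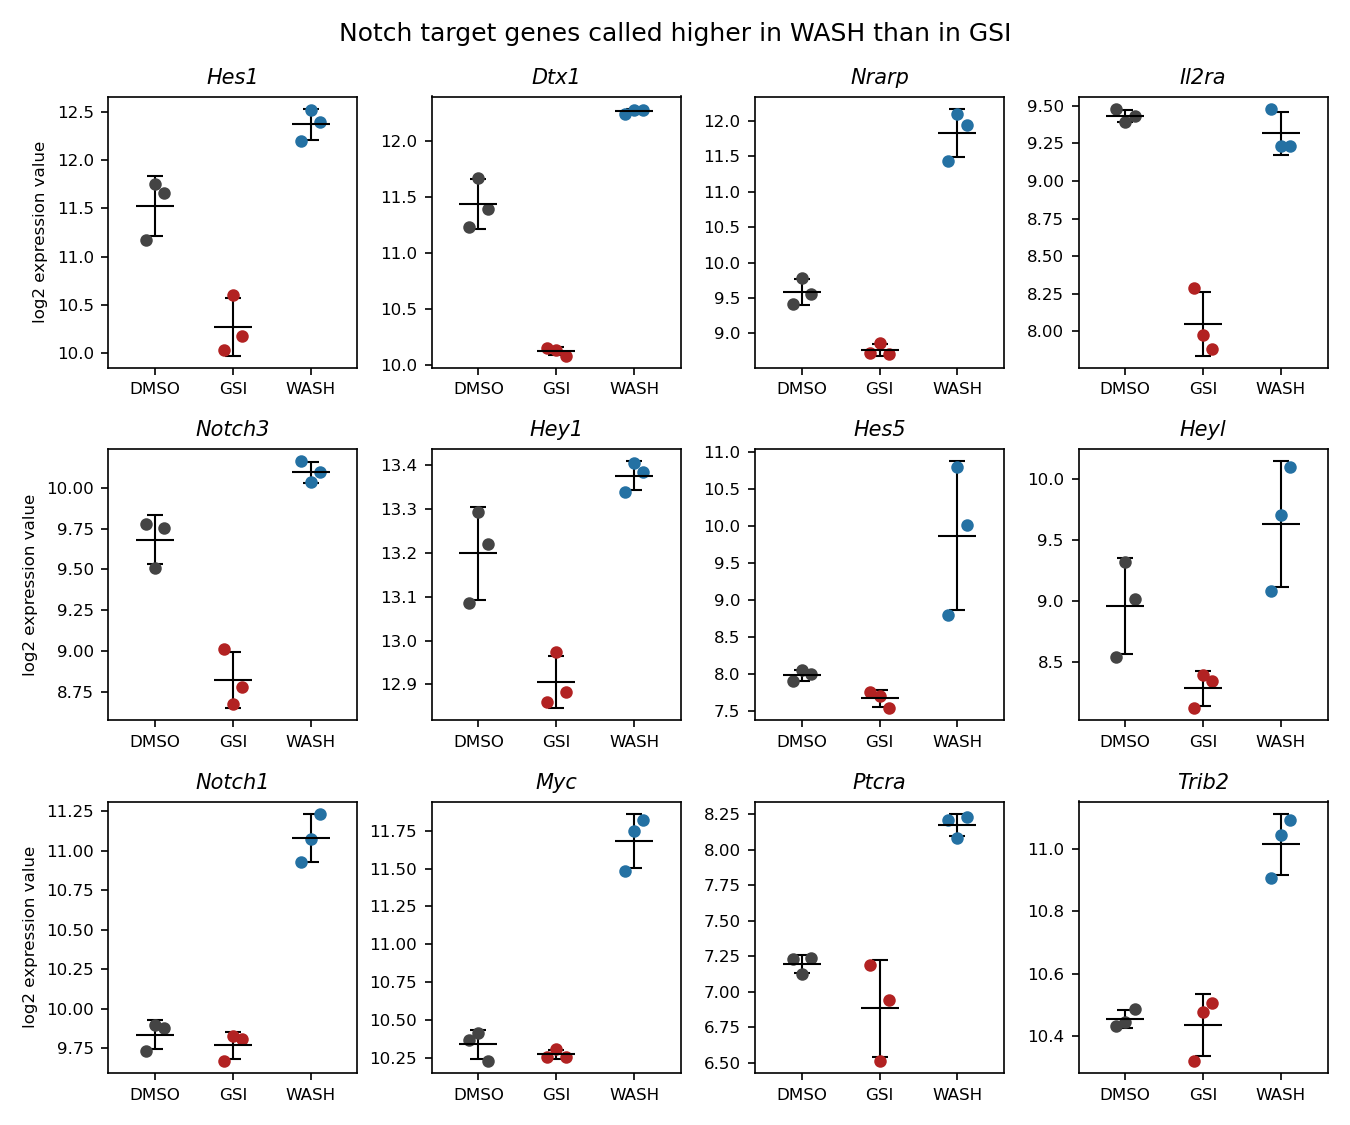
Log2 expression values (vertical axes, which do not start at 0 and differ between genes) of the 12 Notch target genes that rose on washout. Points are the 3 arrays of each group, and bars the mean ± SD. For Myc the GSI and DMSO means lay at 10.28 and 10.34 and the WASH mean at 11.68.

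The comparison of WASH with GSI asked which transcripts changed when the inhibitor was removed while protein synthesis was stopped. Notch target genes led this comparison: 12 of 21 rose and none fell, and 13 rose adjusted over the list alone. Nrarp rose by 3.06 ± 0.15 log2 units (adjusted p = 1.38e-05), an 8.34-fold gain from 8.77 ± 0.08 (SD, n = 3) to 11.83 ± 0.34. Hes5 rose by 2.20 ± 0.38, Dtx1 by 2.14 ± 0.09, Hes1 by 2.10 ± 0.18, the oncogene Myc by 1.41 ± 0.08, Heyl by 1.34 ± 0.25 and Notch1 by 1.31 ± 0.08. Ptcra, the pre-T-cell receptor alpha gene, rose by 1.29 ± 0.14, Notch3 by 1.28 ± 0.10, Il2ra by 1.27 ± 0.10, Trib2 by 0.58 ± 0.06 and Hey1 by 0.47 ± 0.06. Camera called the list higher (adjusted p = 5.09e-26), and among the 22 lists fixed in advance this was the only call that held with an estimated correlation (adjusted p = 0.0367). Fry, which tests whether the genes of a list move on balance one way, gave an adjusted p of 0.000215. Lef1 (0.24 ± 0.05, adjusted p = 0.0863) did not pass over all genes. Hes5 kept its call only without WASH replicate 1 or WASH replicate 2 (adjusted p up to 0.129 without another array). Heyl kept its call only without DMSO replicate 1, WASH replicate 1 or DMSO replicate 2 (up to 0.172).

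Outside that list, Tnfrsf23 rose by 3.21 ± 0.37, Deptor by 3.02 ± 0.11, Tmem255a by 2.55 ± 0.18, B4galnt2 by 2.46 ± 0.11, the synaptic organiser gene Cbln1 by 2.41 ± 0.30, AW011738 by 2.36 ± 0.15 and the Rho-family GTPase gene Rhov by 2.14 ± 0.27. Genes that fell did so by less: Ucma by 0.72 ± 0.08, Antxr2 by 0.70 ± 0.11, Pdp1 by 0.66 ± 0.11, Kctd12 by 0.64 ± 0.09, St3gal1 by 0.64 ± 0.11 and Lzts1 by 0.64 ± 0.10. Sytl2 and Oprd1 each fell by 0.61 (SEs 0.09 and 0.10), Wnt2b by 0.59 ± 0.11 and the kinase anchor gene Akap12 by 0.54 ± 0.06. In limma's test 213 genes rose and 32 fell, and 59 of the former and none of the latter by at least 2-fold, while 1719 genes had an unadjusted p below 0.05. Of the 34 Notch pathway genes Notch1 and Notch3 rose, and the list was not called (adjusted p = 0.371; 4 higher adjusted over the list alone). In the T-cell list Rag2 (by 1.39 ± 0.16), Ptcra and Runx1 (by 0.58 ± 0.08) rose, and the list was called higher (adjusted p = 0.0124; adjusted p = 0.369 with an estimated correlation, and 0.187 without WASH replicate 1). The ribosomal protein list was called higher (adjusted p = 0.00444; adjusted p = 0.487 with an estimated correlation) with a median of 0.03 and no member past the threshold in limma (2 higher at an unadjusted p below 0.05). The p53 targets Fas (by 0.76 ± 0.14) and Plk2 (by 0.95 ± 0.17) rose without a list call (adjusted p = 0.837). Of the other-cell markers Pdgfrb rose by 1.24 ± 0.09, the perforin gene Prf1 by 0.78 ± 0.08 and Epor by 0.42 ± 0.07. The total of 245 became 138 without GSI replicate 3 (131 higher, 7 lower), 145 without WASH replicate 2 (138 and 7), 155 without GSI replicate 2 (143 and 12) and 156 without WASH replicate 3 (145 and 11). Without GSI replicate 1 the fallen genes numbered 20 in place of 32. Antxr2, Oprd1 and Epor lost their calls without any 1 GSI array, WASH replicate 2 or WASH replicate 3 (adjusted p up to 0.0806, 0.0930 and 0.132). Fas lost its call without these or DMSO replicate 1 (0.145). Pdp1 and Sytl2 lost theirs without WASH replicate 1, GSI replicate 2, WASH replicate 2 or GSI replicate 3 (0.127 and 0.0770). St3gal1 lost its call without any 1 GSI array or WASH replicate 3 (0.112), and Lzts1 without GSI replicate 1, GSI replicate 2, WASH replicate 2 or WASH replicate 3 (0.0813). Plk2 kept its call only without DMSO replicate 1, WASH replicate 1 or WASH replicate 2 (0.145), and Wnt2b only without DMSO replicate 1 or DMSO replicate 3 (0.194).

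None of the 159 genes in the 6 growth lists passed in limma's test of WASH against GSI. Protein synthesis was stopped in the 6 h of washout, so a return that needs new protein could not be seen. At an unadjusted p below 0.05, 4 were higher and 1 lower. None of the 28 immediate early genes passed either (2 at an unadjusted p below 0.05), and neither did any integrated stress (2), interferon (3), MAF and ETS (2), FOXO quiescence (1), cholesterol (0), myeloid (3) or B-cell (0) list member. The values for Ets1 (-0.13 ± 0.09), Ets2 (0.01 ± 0.05) and Maf (-0.33 ± 0.10) did not pass. Leaving out 1 array gave list calls for cholesterol (without GSI replicate 1, adjusted p = 0.00679), histones (without GSI replicate 2, 0.0470), MAF and ETS factors (without GSI replicate 1 or WASH replicate 3, down to 0.0399), ribosome biogenesis (without WASH replicate 1 or GSI replicate 2, down to 0.0118) and quiescence (without WASH replicate 1, 0.0253).

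**Figure D2:**
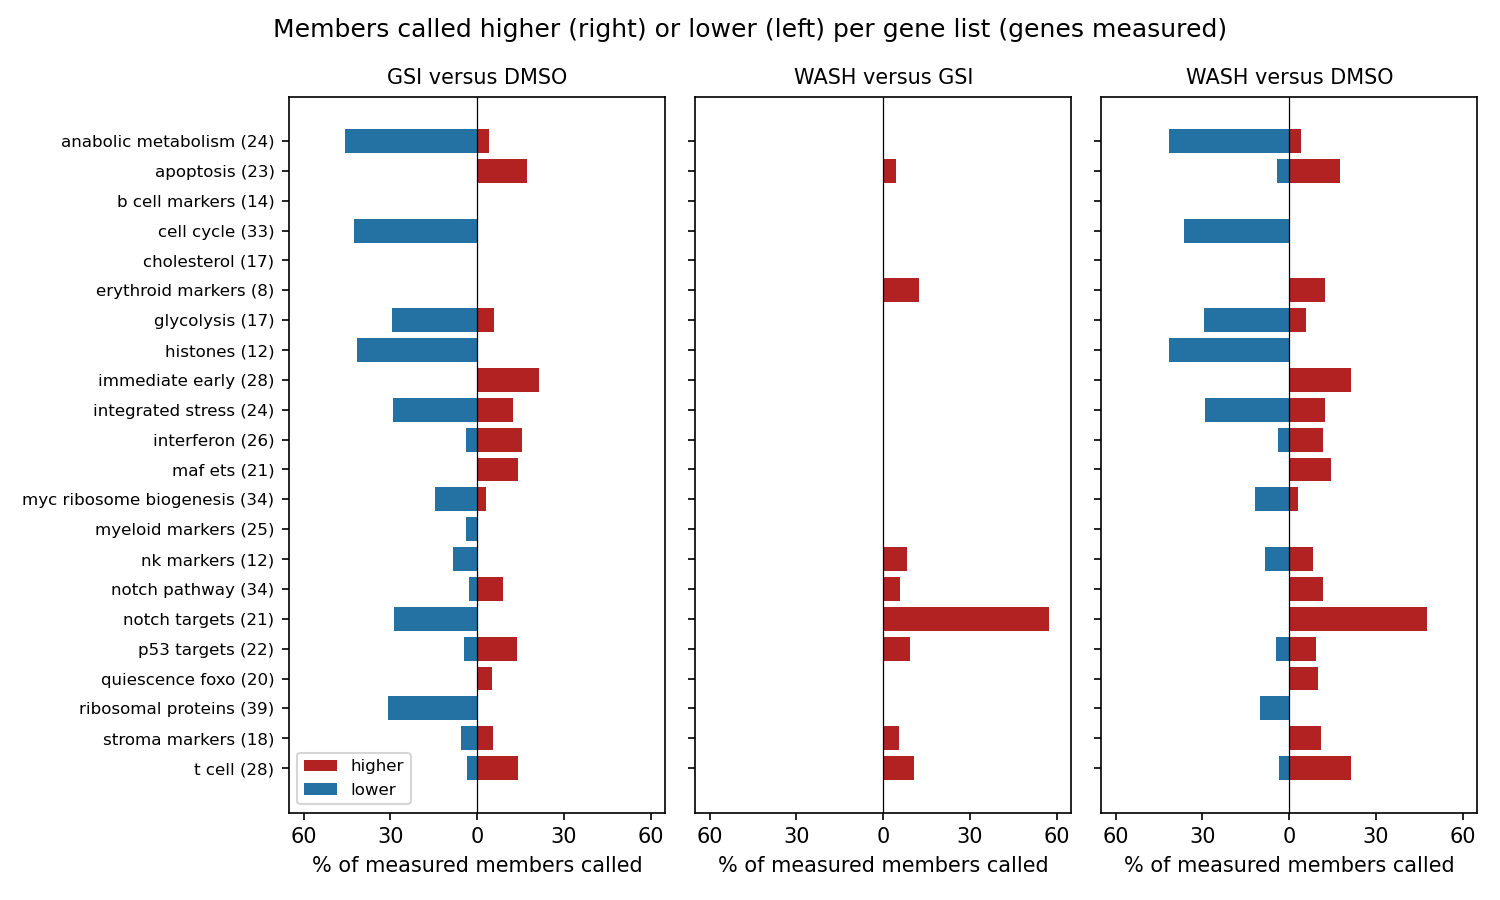
Share of the measured members of each gene list (measured number in brackets) that passed an adjusted p of 0.05 in each comparison, higher to the right and lower to the left. Of the Notch targets 12 of 21 were higher in WASH than in GSI, and 14 of 33 cell cycle genes were lower in GSI than in DMSO.

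The comparison of WASH with DMSO asked how far cells returned to the solvent level after 6 h with protein synthesis stopped. Notch targets ended above it: 10 of 21 were higher than in DMSO and none lower (12 and 1 adjusted over the list alone). Nrarp was higher by 2.25 ± 0.15, Hes5 by 1.88 ± 0.38, Myc by 1.34 ± 0.08, Notch1 by 1.24 ± 0.08, Ptcra by 0.98 ± 0.14, Hes1 by 0.85 ± 0.18 and Dtx1 by 0.83 ± 0.09. Trib2 (0.56 ± 0.06), Notch3 (0.42 ± 0.10) and Lef1 (0.26 ± 0.05) were also higher, and Il2ra (-0.12 ± 0.10) did not differ detectably. The list call (adjusted p = 7.08e-09) was lost with adjusted p = 0.125 with an estimated correlation. Spib lay 3.60 ± 0.19 above DMSO, the interferon gamma gene Ifng 2.63 ± 0.14, Susd2 2.56 ± 0.11, the chemokine gene Ccl3 2.36 ± 0.32, Gbp8 2.35 ± 0.18, Madcam1 2.16 ± 0.08, Tmem255a 2.13 ± 0.18, Fjx1 2.03 ± 0.19 and Rhov 1.92 ± 0.27. At the other end were Mt2 (-2.31 ± 0.04), Cd28 (-1.21 ± 0.12), the amino acid transporter gene Slc7a3 (-1.11 ± 0.17), Aox1 (-1.10 ± 0.11), Notum (-1.08 ± 0.12) and Vegfa (-1.04 ± 0.24). Kazald1 (-1.01 ± 0.08), Fam20a (-0.89 ± 0.14), Pik3r3 (-0.87 ± 0.12) and Fhl4 (-0.85 ± 0.10) followed. In all 771 genes were higher and 613 lower, and 63 and 7 of them by at least 2-fold. The total of 1384 became 730 without WASH replicate 3 (431 higher, 299 lower), 758 without WASH replicate 2 (492 and 266) and 894 without WASH replicate 1 (546 and 348). Without DMSO replicate 1 the lower genes numbered 392. Vegfa kept its call only without DMSO replicate 1 or DMSO replicate 2 (adjusted p up to 0.115 without another array), and Notch3 only without DMSO replicate 1, GSI replicate 1 or GSI replicate 2 (up to 0.113). Hes1 lost its call without DMSO replicate 1, WASH replicate 2 or WASH replicate 3 (up to 0.0895). Hes5 lost its call without DMSO replicate 1, DMSO replicate 3 or WASH replicate 3 (up to 0.0793), and Lef1 without WASH replicate 2 or WASH replicate 3 (up to 0.0751).

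Of the 159 growth genes 40 were lower in WASH than in DMSO, 37 of them among the 52 that fell with GSI. Cycloheximide was present during washout, so a return of these genes that needs new protein could not be seen. Members lower in WASH were 12 of 33 in the cell cycle list, 10 of 24 in the anabolic list, 4 of 39 ribosomal proteins (Rpl13, Rpl30, Rpl32 and Rplp0), 4 of 34 in ribosome biogenesis (Npm1, Nhp2, Mybbp1a and Heatr1), 5 of 17 in glycolysis and 5 of 12 histones. Adjusted over the list alone these counts were 18, 15, 15, 5, 6 and 7. The 6 lists were called lower, with adjusted p from 6.89e-12 for cell cycle to 0.000328 for glycolysis. With an estimated correlation the adjusted p was 0.125 for cell cycle, 0.149 for anabolic, 0.203 for ribosomal protein, 0.449 for ribosome biogenesis, 0.330 for glycolysis and 0.191 for histone genes. Fry called these lists lower (adjusted p up to 0.0352, for glycolysis), except ribosome biogenesis (0.0680). The same 6 immediate early genes that rose with GSI were higher than in DMSO (10 higher and 1 lower adjusted over the list alone; list adjusted p = 7.02e-07; adjusted p = 0.419 with an estimated correlation). Of the integrated stress genes 7 were lower and 3 higher (9 and 4 adjusted over the list alone; 7 and 1 under median centring), with a list call (adjusted p = 0.0145) that was lost with adjusted p = 0.374 with an estimated correlation, and 0.139 without DMSO replicate 2. The T-cell list was higher (6 of 28 higher, 1 lower, and 9 and 2 adjusted over the list alone; adjusted p = 2.49e-05; adjusted p = 0.149 with an estimated correlation), with Ptcra, Rag2 (0.82 ± 0.16), Cd2 (0.62 ± 0.13) and Runx1 (0.41 ± 0.08) among its members. The MAF and ETS list was higher (Etv6, Etv5 and Elk3, 4 adjusted over the list alone; adjusted p = 0.00839; adjusted p = 0.149 with an estimated correlation), as was the Notch pathway list (4 of 34 higher, 7 adjusted over the list alone; adjusted p = 0.0288; adjusted p = 0.435 with an estimated correlation, and up to 0.139 without DMSO replicate 1, WASH replicate 1 or DMSO replicate 3). The stromal list passed through Madcam1 and Pdgfrb (0.59 ± 0.09; adjusted p = 0.0295; adjusted p = 0.352 with an estimated correlation, and up to 0.101 without DMSO replicate 1, DMSO replicate 2 or WASH replicate 2). The cholesterol list was called lower (adjusted p = 0.0481; adjusted p = 0.759 with an estimated correlation, and up to 0.694 without WASH replicate 1, DMSO replicate 2 or GSI replicate 3) with no member past the threshold in limma (5 at an unadjusted p below 0.05). Rplp0 kept its call only without GSI replicate 1, DMSO replicate 2 or GSI replicate 2 (adjusted p up to 0.109 without another array). Mybbp1a lost its call without any 1 DMSO or WASH array (up to 0.106), and Etv5 kept its call only without DMSO replicate 2 (up to 0.146). Elk3 lost its call without DMSO replicate 1, DMSO replicate 3 or any 1 WASH array (up to 0.107), and Rpl30 without DMSO replicate 1, WASH replicate 1 or WASH replicate 2 (up to 0.0997). Rag2 lost its call without WASH replicate 1, DMSO replicate 3 or WASH replicate 3 (up to 0.0624), and Rpl13 and Runx1 without WASH replicate 1 or WASH replicate 3 (up to 0.0540 and 0.0567). Lists for apoptosis (adjusted p = 0.110), interferon (0.430), p53 targets (0.705), FOXO quiescence (0.274), B cells (0.286), myeloid cells (0.430), NK cells (0.975) and erythroid cells (0.766) were not called.

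**Figure D3:**
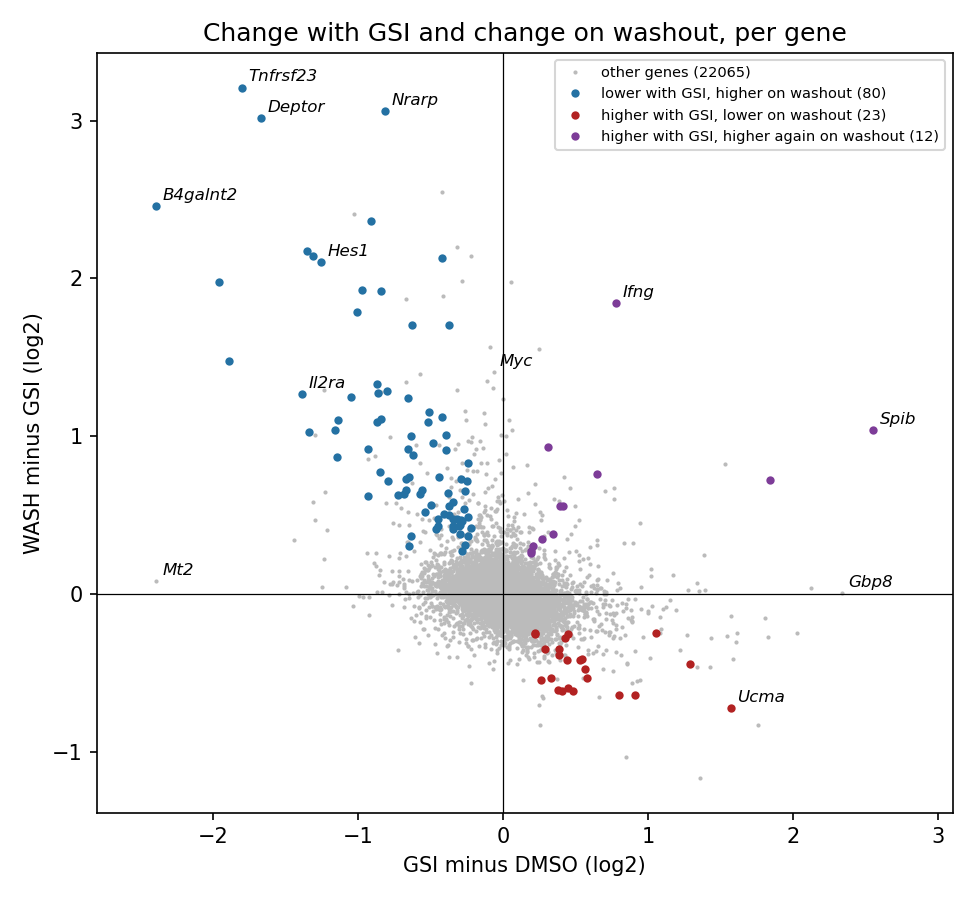
Log2 change with GSI (horizontal, GSI minus DMSO) against log2 change on washout (vertical, WASH minus GSI) for 22180 genes, with genes past an adjusted p of 0.05 in both comparisons in colour. The 80 genes lower with GSI and higher on washout lie at the upper left, and the 23 with the opposite pattern at the lower right.

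Setting both steps side by side, 80 genes fell with GSI and rose on washout. B4galnt2 recovered 103% of its loss, Il10 101%, Il2ra 91.5%, Akap6 89.5% and Serpinb8 78.1%, whereas Tnfrsf23 (178%), Deptor (181%), Hes1 (167%), Dtx1 (163%) and the long non-coding RNA gene Morrbid (119%) exceeded it. The median recovery of these 80 was 146%, and 30 of them ended above DMSO past the threshold, 47 could not be told from it and 3 (Serpinb8, Olfm2 and Kdelr3, the latter pair named after their values were seen) ended below. Having been chosen for a called rise on washout, these genes lean towards high recovery (16.8% over all 814 fallen genes). Independent lists of these sizes would share 7.82 genes, and simulated arrays with no change shared at most 0, or at most 1 when the GSI effects were kept and WASH equalled GSI. Neither simulation held a change on washout, and the latter called at most 1 gene there. Their overlaps had to lie near 0, so they do not show how much the shared arrays add to the real ones. Another 23 genes rose with GSI and fell on washout (1.11 for independent lists, at most 0 in either simulation), led by Ucma, St3gal1, Lzts1, the checkpoint gene Vsir (0.58 ± 0.10, then fell by 0.53 ± 0.10) and the chemokine receptor gene Ccr8 (0.57 ± 0.07, then fell by 0.47 ± 0.07). A further 12 genes rose with GSI and rose again on washout (7.38 for independent lists), among them Spib (by 2.55, then 1.04), Ifng (by 0.78, then 1.84), Susd2 (by 1.84, then 0.73) and Fas (by 0.65, then 0.76). All 12 lay above DMSO, as 2 rises in turn imply. In limma's test 0 genes fell in both steps, against 50 at an unadjusted p below 0.05 in both steps. With the replicate number as a block 3 genes fell in both steps, 123 fell and rose, and 42 rose and fell. Vsir kept its call on washout only without DMSO replicate 1, WASH replicate 1 or DMSO replicate 3 (adjusted p up to 0.162), and Ccr8 lost its call without GSI replicate 2, WASH replicate 2 or GSI replicate 3 (up to 0.0670). The first count became 43 without GSI replicate 3. The second became 3 without GSI replicate 3, 6 without WASH replicate 2, 8 without GSI replicate 2 and 8 without WASH replicate 3.

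The share of the GSI change that returned within 6 h was also taken by size of the change, and the difference between sizes was not tested. Cycloheximide was present in these 6 h, so the shares cover only a return that needs no new protein. The median recovered share over the 814 fallen genes was 16.8% (quartiles 0.806 and 37.0%), and the reversed share over the 768 risen genes 17.7% (1.28 and 39.2%). Over the 101 genes that fell by at least 1.5-fold the recovered share was 45.2%, and over the 24 that fell by at least 2-fold 83.8%. Over the 147 and 41 genes that rose as far, the reversed share was 12.9 and 10.8%. Simulated arrays that kept the GSI effects, with WASH equal to GSI, gave medians of 7.40% and 7.85% over all called genes. Neither this nor the following estimate was made by size of the change. When the genes were chosen without 1 GSI array and the return was measured against that array alone, the recovered share was 15.2, 1.27 and 18.6% for GSI arrays 1, 2 and 3, and the reversed share -0.222, 18.46 and 14.95%. Of the 213 genes that rose on washout 143 ended above DMSO, 67 could not be told from it and 3 ended below, and 121 of the 213 had not been called with GSI. They were chosen for high WASH values, and the same WASH arrays enter WASH against DMSO. Their place above DMSO may thus come in part from the choice. It was not measured against a WASH array left out of the choice. Across genes, which are not independent replicates, the log2 changes of both steps correlated at -0.400 (Spearman -0.434). Both steps share the GSI arrays, so simulated arrays with no change gave -0.501, and those with the GSI effects kept and WASH equal to GSI gave -0.198. The covariance was -0.00965, against -0.00274 from the shared arrays, a difference of -0.00691. With 3 GSI arrays the controls could not be split into 2 sets of 2, so part of the overlaps' excess may come from the shared arrays.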

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

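The report's comparisons leave out probe sets that the platform annotation does not list or that carry several gene symbols, and a signal appeared in both kinds when all 41345 probe sets were tested together with limma. Of the 16004 unlisted probe sets, 203 were called in GSI against DMSO (90 higher), 34 in WASH against GSI (24 higher) and 123 in WASH against DMSO (78 higher). In each comparison this was a smaller share than over all probe sets. Of the 1820 probe sets with several symbols, 61 (13 higher), 10 (all 10 higher) and 33 (14 higher) were called. The 9 other splits of the 6 arrays of each comparison called at most 1, 1 and 0 unlisted probe sets, and at most 0, 0 and 0 with several symbols. Those splits mix both groups, so real differences add to the spread and counts near 0 were largely fixed in advance. The genes behind these probe sets were not analysed here, and no explanation was tested for them.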

How the results depend on the processing

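A gene or list was counted as changed in sign only if it was called in the main fit or in the alternative. By that rule 1 result changed its sign: the reversed share of the risen genes was -0.222% when genes were chosen without GSI array 1. That setting was added for this share after the data had been seen. Medians near 0 of lists that were not called could turn, as for apoptosis with GSI (0.00652, and -0.00389 under median centring). Quantile normalization, median centring, eBayes with trend and robust, the mean of all probe sets and cyclic loess (added after seeing the data) kept the 3 totals, both overlaps and the numbers of called lists within 1.5 times, while member counts of some lists moved more (under median centring interferon with GSI had 1 higher and 2 lower). With the replicate number as a block (replicate block), 123 genes fell and rose, 42 rose and fell, 3 fell in both steps, and the 3 totals were 2032, 359 and 1817. In WASH against GSI 73 genes fell with it, 66 with array weights, 52 without dim genes and 19 over all probe sets, against 32. In WASH against DMSO 361 were lower over all probe sets, against 613. With only the 6 arrays compared, the counts were 914 for GSI against DMSO and 818 for WASH against DMSO, with fewer arrays behind the spread. For genes that rose and fell the count was 41 with array weights, 35 without dim genes and 9 over all probe sets, and the correlation was -0.418 with array weights and -0.441 over all probe sets; the cause was not tested. At an adjusted p below 0.01 the 3 totals were 532, 132 and 574, and the overlaps 34 and 2, by construction of a stricter threshold. With a minimum of 1.5-fold they were 248, 131 and 268, the overlaps 38 and 3, and the recovered share 45.2%. Camera with an estimated correlation called 0, 1 and 0 lists in place of 10, 3 and 14, and fry called 1 in WASH against GSI. Over the 66 list tests of the 3 comparisons, fry lost 6 calls and gained 3. With GSI it called the Notch target list (adjusted p = 0.00664) and the 6 growth lists lower, but did not call the immediate early list (0.0599). Choosing genes without GSI array 2 gave a recovered share of 1.27%.

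Leaving out 1 array in turn gave 722 to 1752 genes for GSI against DMSO, 138 to 247 for WASH against GSI and 730 to 1418 for WASH against DMSO, 43 to 80 that fell and rose, 3 to 28 that rose and fell, a recovered share of 14.5 to 24.9% (highest without GSI replicate 2), a correlation of -0.455 to -0.373, and 3 to 5 lists in WASH against GSI (5 without GSI replicate 1 or GSI replicate 2). Some counts rose above those from all 9 arrays, the highest without DMSO replicate 2 for both comparisons with DMSO. Of 373 results for single genes, 214 of them called, 3 lost and 20 gained a call with the block, and 4 or fewer lost it under each of the other scalings. The number of arrays, and dim signals near background, limit what can be called.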

Other observations

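Some further genes were named after their values were seen, and no list was tested for them as a group. The costimulatory receptor genes Tnfrsf4 (1.54 ± 0.16 log2 units, SE, n = 3 arrays per group) and Tnfrsf9 (1.35 ± 0.10), the glycoprotein gene Cd52 (1.15 ± 0.07), the checkpoint ligand gene Cd274 (1.13 ± 0.14), the cytokine gene Il23a (1.09 ± 0.10), the chemokine gene Ccl4 (0.88 ± 0.18) and the activation marker Cd69 (0.79 ± 0.04) were called higher with GSI. Each was also called higher in WASH than in DMSO, by 0.72 ± 0.18 for Ccl4 to 1.38 ± 0.10 for Tnfrsf9. The T-cell list fixed in advance was not called with GSI (adjusted p = 0.197). Mt1 fell by 0.77 ± 0.08 beside Mt2, and Id3, an inhibitor of E-protein factors, fell by 0.72 ± 0.11. Of 10 measured guanylate-binding protein genes, Gbp4, Gbp8, Gbp9, Gbp10 (1.44 ± 0.09) and Gbp11 (0.32 ± 0.08) rose and none fell, as under all 3 other scalings, and none was called on washout (2 lower at an unadjusted p below 0.05).

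The tests of the washout excess, and those of interferon and shared probes for the Gbp genes, were chosen only after the results were seen. The Gbp genes prompted a test of 32 NF-kB target genes whose values had not been looked at, of which 30 were measured. In GSI against DMSO 11 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.26, and camera gave p = 1.36e-10 (p = 0.0118 with an estimated correlation). Icam1 (1.17 ± 0.10), Ltb (1.08 ± 0.10), Tnip1 (0.91 ± 0.07), Nfkbie (0.85 ± 0.08) and Nfkb2 (0.82 ± 0.08) led it, Ebi3 fell by 0.56 ± 0.11, and none was called on washout (3 at an unadjusted p below 0.05). The interferon list does not decide whether an interferon response raised the Gbp genes: its median was -0.17 (SD 0.411, 26 genes) against 0.29 over all 10 Gbp genes, but 4 of its members, Ddx58 (0.76 ± 0.11) among them, were called higher and 1 lower (4 and 6 adjusted over the list alone), and Ifng rose by 0.78 ± 0.14. Whether near-identical Gbp genes share probes stays open too, since 0 probe sequences were used. Raised NF-kB activity during inhibition is a candidate explanation, as a hypothesis. NF-kB binding or nuclear RelA measured in each group, with and without cycloheximide, would test it. All groups had cycloheximide, so whether the NF-kB targets rise with GSI in its absence is not known.

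Cyclic loess was chosen after the lists had been seen. The 6 growth lists called lower with GSI hold bright genes, so a brightness-dependent shift between arrays could lower them. Among 10000 random lists of like brightness, medians as low as observed made up 0% for anabolic metabolism, 0% for the cell cycle, 0.02% for glycolysis, 0% for histones, 0.07% for ribosome biogenesis and 0% for ribosomal proteins. The typical median of such random lists lay between -0.0103 (for ribosomal proteins) and -0.000196 (for the cell cycle). After cyclic loess, which removes such shifts, 91.6% of the growth lists' median change of -0.17 remained. With so little shift left to remove, that outcome was nearly fixed in advance. The lists of like brightness argue against that shift as the whole cause, and lower growth under inhibition remains a hypothesis, which cell counts or DNA synthesis measured in each group would test.

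Genes that rose on washout had a median of 0.45 above DMSO. Part of this excess may come from choosing the genes for high WASH values, and that part was not estimated. A shift of the whole array scale was not decided: the median of all genes was -1.05% of that excess, which normalization between arrays fixes near 0. A response to replating alone is argued against by the design, since it leaves no difference between groups replated alike, and 0 groups were replated at other times than DMSO. Cycloheximide alone is argued against in the same way, since 0 groups had another dose than DMSO, but cycloheximide acting together with washout cannot be told apart from washout itself, because 0 groups lacked it. A rebound of Notch activity after release may contribute, as a hypothesis that cleaved Notch1 measured in each group, with and without cycloheximide, would test.

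Other groupings of the arrays were tried for each count. The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. The real split called 1582, 245 and 1384 genes in GSI against DMSO, WASH against GSI and WASH against DMSO, and the other splits at most 0 in each, so 1 of 10 splits reached the real count each time. Each other split mixes both groups, so real differences between them add to the spread. Gene counts near 0 were thus largely fixed in advance and are no check on the real counts. For lists the real counts were 10, 3 and 14 and the highest others 10, 9 and 12, with 2, 7 and 1 of 10 splits reaching the real count. In GSI against DMSO the 3 other splits that part all same-numbered pairs called 0 genes each and at most 7 lists, and the 6 that part 1 pair called 0 genes each and at most 10 lists. For the overlaps 100 regroupings of the 9 arrays were drawn, the real one included. The 80 genes that fell and rose and the 23 that rose and fell were each reached by 2 of the 100. The other regrouping that reached them (356 and 320 genes) named all 3 DMSO arrays GSI, which follows the structure of the samples, and all others gave 0. Where a regrouping mixes the groups, an overlap near 0 was likewise largely fixed in advance.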
